A study of Homo sapiens with 6 samples.

How the data were processed

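Polyadenylated RNA was measured by stranded mRNA sequencing in 6 libraries of DIvA cells, a line derived from the human osteosarcoma line U2OS in which the restriction enzyme AsiSI, fused to a hormone-binding domain, enters the nucleus and cuts DNA once 4-hydroxytamoxifen (4-OHT) is added. Per the labels, 3 libraries came from cells with wild-type p53 and 3 from cells in which p53 was knocked out, and all received 300 nM 4-OHT for 5 h. Groups and replicate numbers were taken from the sample titles. No untreated cells were among the samples, so the effect of 4-OHT itself was not analysed here.

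The authors deposited a table of raw counts per gene symbol, with 55882 rows and 1 column per library, and no per-sample column was left unused. Per the submitters' processing notes, fastp 0.21.0, HISAT2 2.1.0 and DESeq2 1.3.6 were used with the human build GRCh37, also called hg19. The counting tool, the annotation and the strand setting of the count are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies such as HSPA1A and HSPA1B, the histone genes and the protocadherin cluster are uncertain as single genes. The deposited comparison table of the authors holds a mean signal of normalised counts, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value per gene. It also marks genes that intersect a p53 cistrome. In all its rows the sign of the fold change was opposite to that of the test score, and CDKN1A was positive, so its log2 fold change was read as p53 WT over p53 KO.

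Total counts were 79767519, 67889247 and 24347609 in p53 WT replicates 1, 2 and 3, and 72621732, 40043686 and 20393909 in p53 KO replicates 1, 2 and 3. A count of 0 allows up to 3 counts, which is 0.0376 CPM (counts scaled to library size) in the deepest library and 0.147 CPM in the shallowest. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The 10 most abundant genes took 6.05% to 6.76% of the counts of a library. Replicates of a group were not copies of each other: the lowest chi-square per degree of freedom between 2 of them was 16.7, over genes with at least 20 counts in the pair.

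Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test, with robust estimation, TMM factors between 0.979 and 1.02 and the filterByExpr filter, which left 22352 genes. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called past the threshold. CPM values are scaled with the TMM factors and given as mean ± SD. Log2 fold changes are p53 KO over p53 WT, and their standard error (SE) was taken as the size of the fold change divided by the square root of the F statistic. The labels do not say whether the replicates were separate cultures, nor how many knockout clones were used. The p-values weigh the difference between groups against the spread between these samples. They therefore do not extend to other cultures or knockout clones.

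A set of 29 gene lists was fixed before the data were examined, as were the tests, most of the other settings and the rule for the genes named. Of 1006 distinct genes in the lists, 926 matched by symbol, 55 by their GENCODE 29 symbol and 24 by a RefSeq synonym, and 1 did not match. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over the 29 lists. The test was repeated with an estimated correlation and with fry. The rule named CDKN1A and MDM2, then the 7 largest increases and the 7 largest decreases. These had an adjusted p under 0.05, a mean of at least 5 CPM, groups that did not overlap and a symbol that was not a clone name. It then took the 3 members with the smallest adjusted p of each list past the threshold, and 2 members of each other list. Some genes that the rule names are not reported here.

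Alternatives were RLE, upper-quartile and no composition factors, no filter and a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. Added after seeing the data were a fit with the local median of the 50 nearest genes taken off as an offset, and a count without genes in shifted runs. Gene order came from RefSeq on GRCh38.p14, another build than that of the authors, so that positions are not printed. The ordered set held 12097 protein-coding genes with a mean of at least 2 CPM. A run was a stretch of at least 25 genes whose running median over 51 genes was over 0.4 in size on the log2 scale. The first and last 25 genes of each chromosome had no running median and could not be in a run.

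The tests were tried on simulated counts with the means, spread and depths of these libraries. There were 200 changed genes, and a list of 40 more genes shifted by -0.8 on the log2 scale. For p53 KO against p53 WT, over 21542 simulated genes tested, 35.8% of 67 genes changed by 0.5 on the log2 scale were recovered, 67.2% of 67 changed by 1 and 90.9% of 66 changed by 2. Of all calls, 5.16% were genes simulated without a change. Far more genes passed in the data, which makes the adjustment less strict there, so these shares do not give the recovery in the data. A simulated run of 120 genes shifted by 0.7 in a shuffled order was found with 71.7% of its genes, and no gene outside it was placed in a run.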

Results

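The series compared gene expression in DIvA cells with and without p53 after DNA cutting was induced. Its title concerns how chromatin organisation shapes the way nuclear factors explore the nucleus. The comparison shows which transcripts differ between p53 WT and p53 KO cells, where p53 is a transcription factor activated by DNA damage. Other differences between the cell populations are not separated from the loss of p53 in any result below. There were 3 p53 WT libraries and 3 p53 KO libraries, all from cells given 300 nM 4-OHT for 5 h. Total counts ranged from 20393909 to 79767519. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.954 to 0.979 within groups and 0.924 to 0.946 between them. Mitochondrially encoded genes took 4.79% to 4.92% of the counts in p53 WT libraries and 5.11% to 5.43% in p53 KO libraries.

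CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, fell from 542 ± 27.0 CPM (SD, n = 3) to 45.8 ± 3.68 CPM (SD, n = 3), a log2 fold change of -3.56 (SE 0.10). MDM2, the ubiquitin ligase that p53 induces and that degrades p53, fell from 221 ± 29.6 to 57.6 ± 13.3 CPM (SD, n = 3), a log2 fold change of -1.93 (SE 0.16). The ranges of the groups did not overlap for CDKN1A or MDM2.

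Known p53 target genes were lower without p53. Of 74 tested members of the 3 p53 target lists, 51 were lower in p53 KO and 1, FUCA1, was higher. FUCA1, a lysosomal fucosidase named after its values were seen, had a log2 fold change of 0.60 (SE 0.20, adjusted p = 0.0376 by edgeR), and 0.55 (adjusted p = 0.0676 by edgeR) after the local median of neighbouring genes was taken off, a setting chosen after seeing the data. Among targets for arrest and feedback, 14 of 20 fell and 14 fell when adjusted over the list alone, with a median log2 fold change of -1.50. BTG2, an antiproliferative gene, fell from 78.9 ± 2.07 to 10.0 ± 1.92 CPM, and PHLDA3, an inhibitor of AKT signalling, fell from 138 ± 12.9 to 24.7 ± 3.13 CPM (SD, n = 3). The list passed camera (adjusted p = 3.18e-08), with adjusted p = 0.0803 when the correlation was estimated.

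Of 18 tested targets for cell death, 15 fell, and 15 fell when adjusted over the list alone, with a median of -1.23. FAS, a death receptor, fell from 67.1 ± 4.62 to 5.63 ± 1.08 CPM, EDA2R, a receptor of the tumour necrosis factor family, from 56.7 ± 6.30 to 5.91 ± 1.02 CPM, and BBC3, which encodes PUMA, from 43.3 ± 2.86 to 8.48 ± 1.52 CPM (SD, n = 3). FAS lies in a stretch of chromosome 10 where neighbouring genes were also lower, and its log2 fold change was -3.58 before and -3.05 after the local median was taken off. Of 36 targets for repair and metabolism, 22 fell, or 24 when adjusted over the list alone, with a median of -0.75. DDB2 and XPC, which recognise damaged bases in nucleotide excision repair, had log2 fold changes of -2.50 (SE 0.11) and -1.52 (SE 0.11), and RRM2B, a subunit of ribonucleotide reductase, had -2.65 (SE 0.16). Both lists passed camera (adjusted p = 2.15e-08 and 2.53e-07) and also with an estimated correlation (adjusted p = 0.0427 for each).

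**Figure D1:**
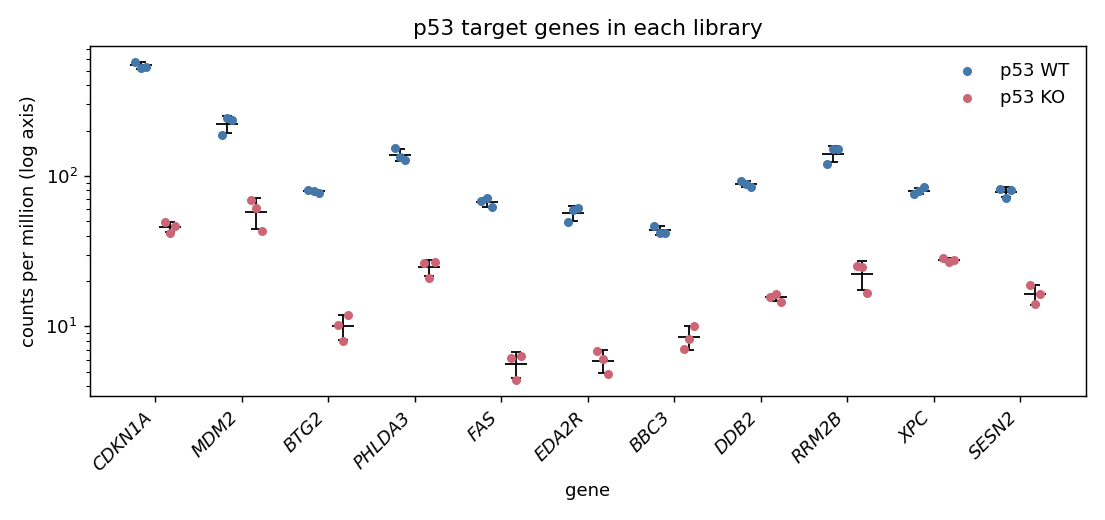
CPM on a log axis for 11 p53 target genes, with a point for each of the 3 p53 WT and 3 p53 KO libraries and black marks for the mean ± SD. CDKN1A lay at 542 CPM on average in p53 WT and at 45.8 CPM in p53 KO.

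Across all genes, 5924 of 22352 passed the threshold, 2697 higher and 3227 lower in p53 KO, and 2068 of them differed at least 2-fold. The groups did not overlap for 40.8% of tested genes, where chance gives 10%. Among the largest increases, CDH11, a cadherin of mesenchymal cells, had 3 counts over the p53 WT libraries and 2613 over the p53 KO libraries. The ratio per scaled total count was 1099 (95% exact binomial interval 376 to 5332, counting error only), and CDH11 lies in a stretch of chromosome 16 with higher neighbours. PLCB2, a phospholipase C, rose from 0.143 ± 0.126 to 16.98 ± 2.05 CPM, and KLK6, a secreted serine protease, from 2.38 ± 0.439 to 63.3 ± 9.17 CPM (SD, n = 3). FAM65B, SDPR, RRAD and ANKRD2 had log2 fold changes of 5.09, 4.42, 4.38 and 4.23, and RRAD lies in the same stretch as CDH11. Among the largest decreases, XYLT1, a xylosyltransferase that starts glycosaminoglycan chains, fell from 83.4 ± 18.2 to 3.86 ± 1.04 CPM, and WNT5B, a secreted WNT ligand, from 63.5 ± 6.85 to 3.88 ± 1.08 CPM (SD, n = 3). CSMD3, ABCC9, TRIM22, MYH16 and OLFM1 had log2 fold changes of -4.72, -4.18, -4.17, -4.16 and -3.97, and OLFM1 lies in a stretch of chromosome 9 with lower neighbours.

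Heat shock chaperones were higher in p53 KO. Of 21 members 15 rose and 0 fell over all genes, and 16 rose and 1 fell when adjusted over the list alone, with a median of 0.50. The member that fell over the list alone, HSP90AA1, named after its values were seen, had -0.24 in the stretch of chromosome 14 with lower neighbours, and 0.68 (adjusted p = 0.000157 by edgeR) after the local median was taken off. CRYAB, a small heat shock protein, rose from 5.47 ± 1.73 to 50.3 ± 11.6 CPM (SD, n = 3), in a stretch of chromosome 11 with higher neighbours. HSPA1A and HSPA1B, near-identical copies of inducible HSP70 whose reads cannot be assigned with certainty, rose by 1.99 (SE 0.15) and 1.87 (SE 0.21) on the log2 scale. The list passed camera (adjusted p = 6.63e-05), with adjusted p = 0.157 when the correlation was estimated.

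Genes of the cell cycle were more often higher. Of 46 G1/S and replication genes 17 rose and 5 (RRM2, POLE2, E2F7, UHRF1 and CDC45, named after their values were seen) fell, with 19 and 6 when adjusted over the list alone. MCM2, a subunit of the replicative helicase, rose from 167 ± 8.45 to 311 ± 8.16 CPM, and MYBL2 from 342 ± 10.9 to 554 ± 47.8 CPM (SD, n = 3). GINS2 had a log2 fold change of 1.12 (SE 0.12) and lies in the stretch of chromosome 16 with higher neighbours. The list passed camera (adjusted p = 0.0102), with adjusted p = 0.157 when the correlation was estimated. Of 52 G2/M and mitosis genes 16 rose and 6 fell, with 17 and 7 when adjusted over the list alone. PRC1, CCNB1 and UBE2C had log2 fold changes of 1.14, 0.73 and 0.77. After the local median was taken off 14 G1/S genes were higher and 2 lower, and 16 G2/M genes were higher and 2 lower. These were partly other genes: 10 of the 17 higher and 1 of the 5 lower G1/S genes kept their call. For G2/M, 10 of the 16 higher and 1 of the 6 lower genes kept their call. The G2/M list passed camera (adjusted p = 0.0437), with adjusted p = 0.544 when the correlation was estimated. It did not pass in 5 of the 6 fits that left out 1 library, where adjusted p by camera was 0.13, 0.0666 and 0.0527 without p53 WT replicates 1, 2 and 3, and 0.137 and 0.075 without p53 KO replicates 1 and 2.

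Matrix and sterol genes were more often lower. Of 50 extracellular matrix and adhesion genes 25 fell and 7 rose, with 28 and 7 when adjusted over the list alone, and the median was -0.40. COL6A3, a collagen VI chain, fell from 265 ± 48.5 to 41.7 ± 7.92 CPM, and TNC, tenascin C, from 667 ± 85.9 to 176 ± 16.4 CPM (SD, n = 3). CDH11, the third member named, went the other way. Camera gave adjusted p = 0.000868, and adjusted p = 0.424 with an estimated correlation. Of 29 sterol synthesis genes 14 fell and 1, EBP, rose, with 14 and 2 when adjusted over the list alone. SCD, a fatty acid desaturase, and SQLE, squalene epoxidase, had log2 fold changes of -1.03 (SE 0.09) and -0.78 (SE 0.10). EBP had 1.09 (SE 0.15) in a stretch of the X chromosome with higher neighbours, and 0.40 (adjusted p = 0.0813 by edgeR) after the local median was taken off. Camera gave adjusted p = 0.00266 for the sterol list, and adjusted p = 0.544 with an estimated correlation.

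**Figure D2:**
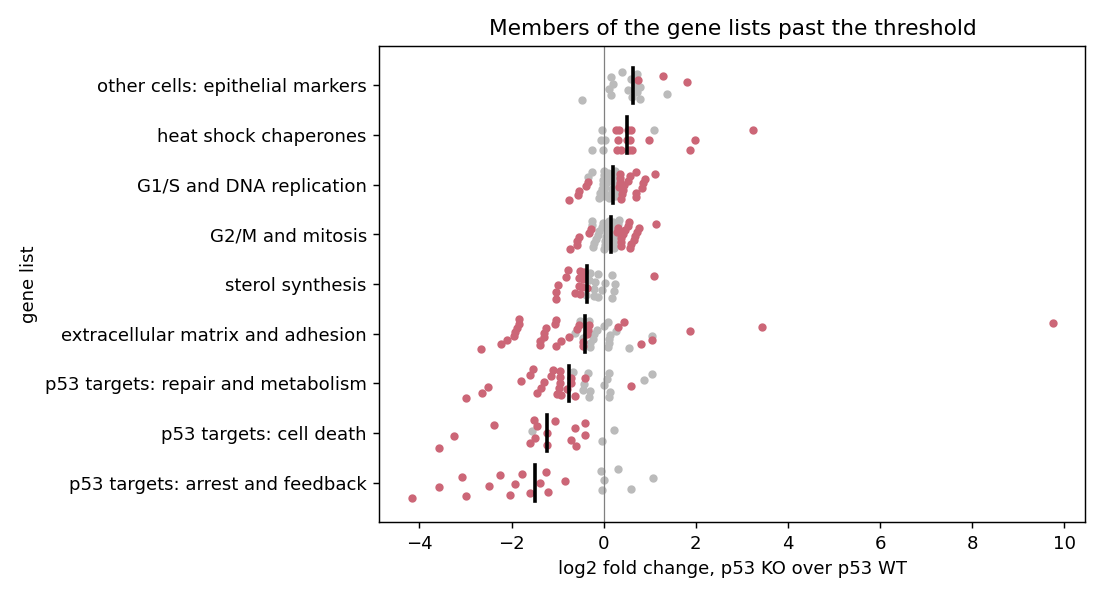
Log2 fold change of p53 KO over p53 WT for each tested member of the 9 lists past the threshold, with red points for members past the threshold, grey points for the others and a black bar at the median. The medians run from -1.50 for p53 targets of arrest and feedback to 0.64 for epithelial markers.

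Of the lists of markers of other cell types, the epithelial one passed camera (adjusted p = 0.00951, or adjusted p = 0.424 with an estimated correlation). Of its 18 members 3 rose, and 3 when adjusted over the list alone. KRT8, a keratin, rose from 143 ± 5.95 to 239 ± 14.4 CPM (SD, n = 3), while CLDN7 and ESRP2 rose from 1.23 and 0.532 CPM to 3.02 and 1.95 CPM. ESRP2 lies in the stretch of chromosome 16, and its adjusted p by edgeR was 0.0783 after the local median was taken off. Its call was also lost without p53 WT replicate 2, at 1.64 against 1.82 on the log2 scale. The endothelial, leukocyte and neuronal lists did not pass (adjusted p = 0.311, 0.189 and 0.655 by camera). Of 11 endothelial markers 3 rose (ROBO4, ERG and SOX18) and 4 when adjusted over the list alone. ERG, at 0.66 on the log2 scale, lost its call after the local median was taken off (0.47, adjusted p = 0.0986 by edgeR), as did SOX18. The call of ERG was also lost without p53 WT replicates 1 or 3 or p53 KO replicates 1 or 2, at 0.55, 0.66, 0.58 and 0.60. Of 8 leukocyte markers 3 rose, ITGB2, CORO1A and CD74, with 10.9 ± 0.925 CPM (SD, n = 3) of ITGB2 and 5.87 ± 1.20 CPM (SD, n = 3) of CORO1A in p53 KO. Of 15 neuronal markers 5 fell and 3 rose, and the median (0.16) differed in sign from the mean (-0.28) and the test. NEFL had -1.25 (SE 0.10), and NCAM1 had 0.92 (SE 0.14), or 0.36 with adjusted p = 0.1 by edgeR after the local median was taken off.

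No other list passed camera. For DNA repair, 8 of 34 end joining and damage signalling genes rose and 4 (FAM35A, RNF168, XRCC6 and POLL) fell (adjusted p = 0.235 by camera), and 8 and 5 when adjusted over the list alone. After the local median was taken off 6 were higher and 3 lower, and 4 of the 8 and 2 of the 4 kept their call. ATR, named after its values were seen, turned from called higher to called lower. FAM35A, a shieldin subunit, and RNF168, a ubiquitin ligase at breaks, had -0.97 (SE 0.12) and -0.76 (SE 0.11), and FAM35A shares the stretch of chromosome 10 with FAS. Of 38 homologous recombination and Fanconi anaemia genes 8 rose and 7 fell (adjusted p = 0.852 by camera), with 9 and 8 when adjusted over the list alone. After the local median was taken off 5 were higher and 6 lower, and 3 of the 8 and 6 of the 7 kept their call. FANCA had 0.88, and XRCC3 had -1.04 but -0.13 (adjusted p = 0.495 by edgeR) after the local median was taken off. Of 66 chromatin architecture and lamina genes 19 rose and 7 fell (adjusted p = 0.189 by camera), with 24 and 9 when adjusted over the list alone. After the local median was taken off 11 were higher and 3 lower, and 8 of the 19 and 2 of the 7 kept their call. HMGA2, an architectural chromatin protein, had -0.84 (SE 0.12). SUV39H1, a histone H3 methyltransferase, had 0.85 (SE 0.12) but lies in the stretch of the X chromosome, and had 0.16 (adjusted p = 0.405 by edgeR) after the local median was taken off. Of 41 histone genes 7 fell and 2 (HIST1H2BM and HIST1H1E) rose (adjusted p = 0.993 by camera), with 6 and 1 when adjusted over the list alone, and 6 and 1 after the local median was taken off. HIST1H2BK and HIST2H2BE had -0.98 and -1.19. The histone median of 0.13 and mean of 0.44 differed in sign from the test. Polyadenylated RNA was sequenced, so histone transcripts that are not polyadenylated are not reliably measured by these values.

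In the stress and signalling lists the members split. Of 34 NF-kB and secreted factors 13 rose and 8 fell, and as many when adjusted over the list alone (adjusted p = 0.189 by camera). Their median of 0.53 and mean of -0.07 differed in sign. SERPINE2, a protease inhibitor, and MMP3, a matrix protease, had -2.25 (SE 0.11) and -3.45 (SE 0.17), MMP3 in the stretch of chromosome 11 whose neighbours were higher. Of 31 immediate early genes 9 fell and 5 rose (adjusted p = 0.582 by camera), with 10 and 5 when adjusted over the list alone. BTG2 was named above, and NR4A1, a nuclear receptor, had 1.55 (SE 0.13). Of 36 genes of amino acid and unfolded protein stress 9 fell and 5 rose (adjusted p = 0.582 by camera), with 10 and 5 when adjusted over the list alone. After the local median was taken off 7 were lower and 3 higher, and 5 of the 9 and 1 of the 5 kept their call. SESN2, also a p53 target, had -2.25 and SLC7A11, a cystine transporter, had -1.81. Of 30 Hippo and TGF-beta targets 8 rose and 8 fell (adjusted p = 0.655 by camera), with 10 and 9 when adjusted over the list alone. After the local median was taken off 5 were higher and 5 lower, and 4 of the 8 that rose and 5 of the 8 that fell kept their call. LTBP2 had -2.10 in a stretch of chromosome 14 with lower neighbours. Of 41 interferon response genes 9 rose and 2, DDX58 and IFIT5, fell (adjusted p = 0.189 by camera), with 10 and 2 when adjusted over the list alone, and 7 and 1 after the local median was taken off. PSMB8 and DTX3L had 0.82 and 0.80.

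Of 36 glycolysis and hypoxia genes 7 fell and 5 rose (adjusted p = 0.982 by camera), with 9 and 5 when adjusted over the list alone, and SLC2A1, a glucose transporter, and CA12 had -1.35 and -1.27. Of 37 autophagy and lysosome genes 8 rose and 7 fell, and as many when adjusted over the list alone (adjusted p = 0.869 by camera). After the local median was taken off 2 were higher and 8 lower, 1 of the 8 that rose and 5 of the 7 that fell kept their call, and the direction by camera turned to lower (adjusted p = 0.491 by camera). NPC1 had -1.13, and MAP1LC3B had 0.90 in the stretch of chromosome 16. Of 50 nuclear oxidative phosphorylation genes 13 rose and 6 fell (adjusted p = 0.189 by camera), with 14 and 7 when adjusted over the list alone. After the local median was taken off 6 were higher and 2 lower, and 4 of the 13 and 2 of the 6 kept their call. SDHD and COX4I1 had 0.77 and 0.80, in the stretches of chromosomes 11 and 16, and 0.20 and 0.25 (adjusted p = 0.214 and 0.15 by edgeR) after the local median was taken off. Of 13 mitochondrially encoded genes MT-ND6, MT-CYB and MT-ND1 rose and MT-ND2 fell, 3 and 1 also when adjusted over the list alone (adjusted p = 0.306 by camera). MT-ND6 and MT-CYB had 0.71 and 0.46. Of 77 ribosomal protein genes 6 fell and 3 (RPS6, RPL13 and RPS21) rose, with 5 and 2 when adjusted over the list alone (adjusted p = 0.852 by camera). After the local median was taken off 0 were lower and 2 higher, so all 6 that fell lost their call, as did RPL13 and RPS21. RPL13 had 0.54, and -0.0074 after the local median was taken off. RPS6 had 0.88, and RPS2 had -0.65 in another stretch of chromosome 16, where neighbours were lower, and -0.16 (adjusted p = 0.378 by edgeR) after the local median was taken off. Of 40 ribosome biogenesis genes 5 rose and 5 fell, and as many when adjusted over the list alone (adjusted p = 0.582 by camera), with 5 and 2 after the local median was taken off. CIRH1A, in the same stretch as CDH11, had 0.85, and WDR43 had -0.76.

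Of 13 nuclear-retained RNAs NEAT1, TUG1 and CCNL2 fell and CCNL1 rose, 3 and 1 also when adjusted over the list alone (adjusted p = 0.655 by camera). CCNL1 had 0.66, and -0.023 after the local median was taken off. NEAT1, the scaffold of paraspeckles, had -0.79 (SE 0.12), and TUG1 had -0.68 in a stretch of chromosome 22 with lower neighbours, and -0.26 (adjusted p = 0.141 by edgeR) after the local median was taken off. Of 17 osteoblast lineage genes 6 fell and 3 (FGFR1, DLX3 and COL1A1) rose, with 6 and 4 when adjusted over the list alone (adjusted p = 0.655 by camera). After the local median was taken off 4 were lower and 5 higher, and the direction by camera turned to higher (adjusted p = 0.937 by camera). Their median of -0.23 and mean of 0.08 differed in sign. SPP1, osteopontin, fell from 64.7 ± 5.99 to 11.02 ± 3.23 CPM, and ALPL, alkaline phosphatase, from 7.49 ± 0.667 to 1.66 ± 1.00 CPM (SD, n = 3).

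The authors' deposited table held 35987 genes, of which 5029 had an adjusted p under 0.05, 2704 higher in p53 WT and 2325 higher in p53 KO. Over 22201 genes with a result in both, 2168 calls higher and 2581 calls lower in p53 KO were shared with the authors' deposited table, and 0 shared calls had opposite signs. Both come from the same counts, so this compares methods, not samples. The authors' deposited table marked 124 genes as lying in a p53 cistrome, all with an adjusted p under 0.05 and higher in p53 WT there. Of these, 123 passed as lower in p53 KO here, or 124 when adjusted over the list alone. The marks were chosen on these samples and are not independent evidence of direction.

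Neighbouring genes often moved together. In genome order, 18 runs held 1544 of 12097 protein-coding genes, 6 runs higher and 12 lower in p53 KO. The longest was a run of 276 genes on chromosome 14, from TRAPPC6B to TRMT61A, with a median log2 fold change of -0.69 and 93.5% of its genes lower. Chromosome 16 held a run of 215 genes from N4BP1 to RNF166 with a median of 0.59, and a run of 68 genes from FAM173A to ZNF200 with -0.50. Further long runs lay on chromosomes 15 (NEO1 to MAN2A2, 0.65), 9 (SLC25A25 to TRAF2, -0.50) and 3 (ACAD11 to KPNA4, 0.69). Between the first and last genes of the runs lay 2138 tested genes of any kind, and 1165 of them (54.5%) passed the threshold by edgeR, which is 19.7% of all calls, against 26.7% of 15005 tested genes with a known position outside runs. Runs were defined by the fold changes of the same comparison, so a higher share of calls in them follows from how they were chosen. Genes at chromosome ends, which had no running median, count as outside runs even if their neighbours shifted. With the local median taken off, a setting chosen after seeing the data, 4423 genes passed, and 51 of the listed p53 targets were lower. Among named genes that kept their call in that fit, the log2 fold change shrank by over 1.5 times to 0.56 for MCM2, 0.57 for GINS2, 0.60 for PRC1, -1.22 for LTBP2, 0.36 for MAP1LC3B and -0.42 for FAM35A. It also shrank to -0.36 for RNF168, 0.34 for FANCA, 0.47 for DTX3L, 0.50 for RPS6, 0.31 for CIRH1A and -0.39 for WDR43.

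**Figure D3:**
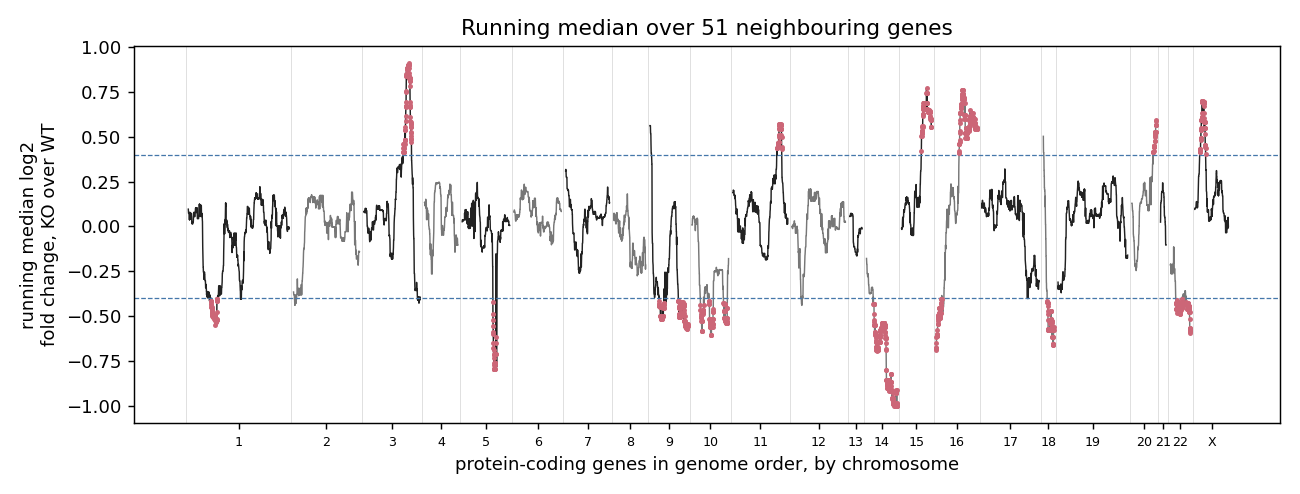
Running median of the log2 fold change of p53 KO over p53 WT across 51 neighbouring protein-coding genes, in genome order by chromosome, with dashed lines at 0.4 in either direction and red points in runs of at least 25 genes. Chromosome 14 held the longest run, with a median of -0.69.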

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

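The settings that took off the local median or left out genes in runs were chosen after seeing the data. No gene named by the rule and no list past the threshold changed direction under the settings run for it. Of genes named after their values were seen, HSP90AA1, CCNL1 and RPL13 changed sign with the local median taken off, to 0.68, -0.023 and -0.0074 on the log2 scale. ATR also changed sign there, from called higher to called lower. The counts of calls over all genes and of p53 targets lower in p53 KO stayed within 1.5 times their main values under RLE, upper-quartile or no composition factors, other filters, DESeq2, limma-voom and the settings for runs. Some counts within other lists moved by more with the local median taken off, as given beside them, and were not run under the other settings. Over all tools and these settings the number of genes past the threshold ran from 4423 to 6762. With an adjusted p under 0.01 it was 3758, 1659 higher and 2099 lower, as a stricter threshold must give fewer. The 51 p53 targets lower in p53 KO became 45 once genes in runs were left out. This setting only takes genes out of the count. Of the arrest, cell death and repair lists of p53 targets, 1, 3 and 4 tested members lay in runs. Of 9 lists past the threshold, 2 passed with an estimated correlation, and fry, which does not compare a list with other genes, gave 15. Calls shared with the authors' deposited table were 1809 at 2-fold in both. Leaving out 1 library gave 4160 to 6059 genes past the threshold, 1872 to 2857 higher and 2288 to 3202 lower, 1792 to 2156 at 2-fold, 49 to 52 p53 targets lower and 8 to 9 lists. It lost 658 to 1817 of the calls and turned 0. No pairing of samples by replicate number was detected: deviations of same-numbered samples correlated at 0.017, 0.034 and -0.029, and 1 of 6 samples correlated best with its own number. Total counts fell with the replicate number in both groups, so pairing is not excluded. With the number as a replicate block 5159 genes passed, 2297 higher and 2862 lower, and the G2/M list did not pass (adjusted p = 0.0799 by camera). Without a filter the NF-kB list passed (adjusted p = 0.038 by camera), and without p53 KO replicate 2 the nuclear oxidative phosphorylation list passed (adjusted p = 0.0399, against 0.189 with all libraries). The cause was not tested. At the depth, spread and group size of these libraries, 35.8% of simulated changes of 0.5 on the log2 scale were found. Far fewer genes changed in the simulation than passed in the data, so the adjustment was stricter and this share is not the recovery in the data.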

Other observations

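Tests of gene order, of held-out genes and of the libraries within each run were chosen after the runs were seen; the others were fixed before their results. Runs of shifted genes lay on 13 of 23 chromosomes. On chromosome 5 all 35 genes in runs lay between PCDHA6 and PCDHGB7, with a median of -0.82. This stretch spans the protocadherin cluster, whose members are uncertain as single genes, so it may be a single locus rather than a wider regional shift. Over all ordered genes, chromosomes 14, 22, 18, 9 and 10 had medians of -0.61, -0.42, -0.32, -0.31 and -0.25, and chromosomes 15 and 16 had 0.25 and 0.24. GDF15, a listed p53 target singled out after its values were seen, had 0.396 ± 0.199 CPM in p53 WT and 0.486 ± 0.309 CPM in p53 KO (SD, n = 3). How reads over overlapping features were counted is not given in the sources used here, so these values are not a measure of whether GDF15 was expressed.

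Runs of shifted genes are the pattern a reader would most want to follow up. Shuffled gene orders reached a running median of 0.452 at most, against 1.00 in the data, none of 1000 orders held a run, and GC content and transcript length, known for 95.9% of the genes, explained 0.67% of the variance of the fold changes, with 92.3% of the genes of the runs still in a run after regression on them. Against single libraries the bound of 0.4 fixed beforehand was passed: p53 KO replicate 3 reached 0.438 against its own group, on chromosome 15 outside the runs, so shifts of 1 library exist. The largest values of p53 WT replicate 1 (0.251) and p53 KO replicate 1 (0.221) lay inside runs, on chromosomes 16 and 10. Those of p53 WT replicates 2 and 3 (0.147 and 0.211) and p53 KO replicate 2 (0.229) lay outside runs. In 18 of 18 runs the p53 KO libraries all lay beyond the p53 WT libraries. The runs were chosen on the difference between the groups in these same libraries, which favours such separation, so no conclusion is drawn from it. Where runs were found on alternate genes, 88.1% of 791 held-out genes moved with them. By another measure, 89.0% of ordered genes in runs moved in the direction of the median of their 50 nearest genes. Outside the runs, chromosome ends included, 63.6% did. Runs were chosen on these fold changes, which favours the higher share. A different DNA copy number of the cell populations may give such shifts, as may regional regulation by p53: the held-out genes do not separate these, DNA was not measured here, and both stay open.

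Regional shifts do not account for the whole set of calls, since 59.5% of those with a known position passed in the same direction once the local median was taken off. The 3 against 3 design allows 10 splits of the libraries, too few for a share under 0.05. The real split gave 5924 calls, 1 split gave as many (the real one), and the highest of the others gave 1 call.

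Higher heat shock chaperones could reflect the knockout line or its handling as well as p53, which the design does not separate. With the local median taken off 15 members were higher past the threshold, 13 of them among the 15 called before it was taken off. Of 21 members 4 lay in runs, 1 in a higher run and 3 in lower runs. This fit could therefore hardly have lowered the count, and no conclusion is drawn from it. With only 1 member in a higher run, such runs cannot account for most of the 15 that rose. Without any 1 p53 KO library at least 11 members passed, which argues against a single deviating library. Clonal differences between the lines stay open and untested.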
